A study of Mus musculus with 9 samples.

How the data were processed

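RNA was measured in 9 libraries of Y-1 mouse adrenocortical cells, 3 each of vehicle (0.05% ethanol), 100 nM dexamethasone for 1 h and 100 nM dexamethasone for 24 h. Per the labels, total RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra RNA kit. The authors deposited a table of raw counts per gene, in the unit counts, with whole numbers in each of the 9 library columns. The same table gives a gene length in bases, an other unit per the file headers, which was not used in any test. The submitters' processing notes name CASAVA 1.8, STAR 2.5, HTSeq 0.6.1 and mm10/GRCm38. Their roles and settings, the strandedness, the read length and the annotation release are not given in the sources used here. Of 54532 gene identifiers, 54495 were also in GENCODE M21, and 98.3% of these had the same start and end, so positions are those in the table on GRCm38. All library columns were matched to a sample (0 left over), and 0 entries named no gene. Within groups, 9 pairs of libraries were checked for duplication: chi-squared per gene ran from 7.42 to 31.26, with 0 identical pairs.

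Total counts ran from 14288753 to 20081705 per library. Levels are CPM, counts scaled to library size, after TMM scaling, as mean ± SD of 3 libraries. Genes were kept by filterByExpr with a minimum count of 10, which left 13988. Each comparison used the quasi-likelihood F test of edgeR 4.0.16 with robust fitting on R 4.3.3, with all 9 libraries in 1 fit without a block. A change was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error is the log2 fold change divided by the root of its F statistic. The comparisons were 1 h against vehicle, 24 h against vehicle, 24 h against 1 h, and the 3 groups together. Limits on 0 counts use 3 counts and cover counting error only.

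The tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. Of 35 gene lists (688 entries, 664 different genes), the 33 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within each comparison. The other 2 hold markers of the adrenal medulla and of macrophages and leukocytes. Each list was also tested with an estimated correlation and with fry, and its members were counted over all genes tested and adjusted over the list alone. Several genes stand on more than 1 list. Among lists that camera did not call, the median, mean and test direction differed in sign for fibroblast and endothelial markers at 1 h, adrenocortical regulators and interferon genes at 24 h, the BCL2 family at both times, p53 targets in all 3 comparisons, and a few others with medians within 0.02 of 0.

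Named genes were chosen by rule. For 1 h and for 24 h against vehicle, the rule takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 2 CPM in the higher group and no overlap between groups. For 24 h against 1 h it takes 5 and 5. Predicted and unnamed gene models are left out of this ranking. For each list it takes at most the 4 called members with the lowest adjusted p. A set of 16 receptor, steroidogenic and glucocorticoid target genes is named whether called or not. By this rule 111 tested genes were chosen, of which 1 is not reported here. Of these, 24 overlap another gene model with counts, in 28 pairs; 2 of the partners passed a test, Gm43909 beside Bhlhe41 and 8030451A03Rik beside Tnc. Genes named outside the rule, which are Zfp36, Glul, Hif3a, Arntl, Lama1, Gadd45b, Slc45a3, Pdp1, Tent5b, 9330159F19Rik, Gm2420, Gm27252, Fdx1, Akr1b7, 9 X-linked genes and partners of overlapping models, complete a count. These, and Egr1, which shows the spread of the 1 h libraries, were chosen after their values were seen.

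The series design describes independent experiments on different days from different passages, and the titles number the libraries, so replicate number was taken as the experiment. Counts with the block had been seen when this was settled, so the fit without a block stayed the reported one. Residuals of libraries with the same number correlated at 0.06 to 0.38 across genes in 9 pairs (6 over 0.1), and those with different numbers at -0.28 to 0.10 in 18 pairs (0 over 0.1). The value with replicate number as a block is therefore given beside the counts of genes called, some of the named genes and list calls that it changes, and the member counts of called lists and of steroidogenesis that it moves by over 1.5 times. Member counts of the other lists with the block are not given. The alternatives were the block, DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter at 1 CPM in 3 libraries, a threshold of 0.01, only the 2 groups compared, and leaving out each library. A GC correction, an offset per library from a spline with 6 degrees of freedom on transcript GC content, was added after the data were seen, alone and with the block.

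The test was tried on simulated data with 13753 genes and known changes, set only in genes with a mean over 1 CPM. Without a GC trend it recovered 46.3% of 1.5-fold, 77.6% of 2-fold and 98.5% of 4-fold changes at 1 h, and 47.8%, 73.1% and 97.0% at 24 h. False calls made up 8.64% of calls at 1 h, 7.64% at 24 h and 4.18% between 24 h and 1 h. These shares, and those that follow, each come from 1 simulated dataset. The nominal 5% is an average over datasets, so they cannot show whether the test exceeds it. With the block, false calls made up 12.3%, 6.49% and 6.75%. The simulated data held no effect of replicate number, so these shares do not describe the block in the real libraries. With the GC trends seen in these libraries and no correction, as in the reported test, and 13757 genes, it recovered 31.3% of 1.5-fold, 71.6% of 2-fold and 93.9% of 4-fold changes at 1 h. At 24 h it recovered 31.3%, 73.1% and 100.0%, and between 24 h and 1 h 36.6%, 73.3% and 98.5%. False calls then made up 7.75%, 2.16% and 3.87%. The simulated spread was estimated from the real libraries without a GC correction, so it already held their GC scatter. The added trends counted that scatter a second time, so this recovery can be lower than that of the reported test. In 10 simulations of unchanged groups there were at most 0 calls at 1 h and 2 among the 3 groups. Camera called at most 1 list in them, and 0 lists with an estimated correlation. Each simulated gene was drawn independently, whereas the estimated correlation of lists at 1 h in the real libraries ran from -0.07 to 0.79. These list counts therefore cannot show how often camera calls unchanged lists whose members are correlated. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. No other files or assays of the study were used here.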

Results

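Y-1 cells are a mouse adrenocortical tumour cell line that makes steroids. RNA sequencing measured their transcripts after dexamethasone, a synthetic glucocorticoid that acts through the glucocorticoid receptor. The 9 libraries formed 3 groups of 3: vehicle (0.05% ethanol), 100 nM dexamethasone for 1 h and 100 nM dexamethasone for 24 h. The vehicle libraries are labelled 1 h, so the 24 h libraries also differed from them in time in culture, and the design cannot separate this from the treatment. Total counts were 16652657, 15413862 and 20077014 in vehicle libraries 1, 2 and 3. They were 16167634, 20081705 and 16916431 in the 1 h libraries, and 14288753, 16537011 and 17476058 in the 24 h libraries. Of 54532 genes in the table, 13988 had enough counts to be tested. The common biological coefficient of variation between libraries of a group was 13.9%. Libraries also differed in how their counts followed GC content. Across genes, which are not independent replicates, the rank correlation of a library's deviation with transcript GC content was 0.44, 0.44 and -0.38 in vehicle libraries 1, 2 and 3. It was -0.41, 0.04 and -0.25 in the 1 h libraries and 0.32, 0.30 and -0.42 in the 24 h libraries.

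The first comparison asked which transcripts changed within 1 h of dexamethasone. Per1 (ENSMUSG00000020893, GRCm38 chromosome 11, 69095217 to 69109960), a clock gene that the glucocorticoid receptor induces directly in many cells, had the lowest adjusted p. It rose from 32.5 ± 5.02 CPM in vehicle to 237 ± 13.6 CPM at 1 h (SD, n = 3), a log2 fold change of 2.87 (SE 0.13, edgeR adjusted p = 6.4e-08). Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), a subunit of the AP-1 transcription factor, had the largest named rise, from 2.91 ± 0.527 to 106 ± 55.2 CPM (log2 fold change 5.18, SE 0.43, adjusted p = 1.3e-04). Srf, the transcription factor that drives many growth-factor responsive and actin genes, rose from 84.7 ± 7.19 to 215 ± 9.68 CPM (1.34, SE 0.10, adjusted p = 1.1e-05). Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), an inhibitor of cytokine receptor signalling, fell from 19.9 ± 4.43 to 7.82 ± 1.24 CPM (-1.34, SE 0.19, adjusted p = 0.0019).

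In all, 191 genes changed at 1 h, 131 higher and 60 lower, and 77 of them by at least 2-fold (67 higher, 10 lower). The 3 treated libraries lay wholly above or below the 3 vehicle libraries for all 191; this held for 17.2% of all genes tested, where chance gives 10%. With replicate number as a block, because the series design describes independent experiments on different days, 454 genes passed. With the GC correction, 298 did. Without 1 library the count was 104 (vehicle 1), 90 (vehicle 2), 438 (vehicle 3), 113 (1 h library 1) or 115 (1 h library 3). Lower genes numbered 15, 14, 142, 22 and 18 in these, in that order, against 60 with all libraries.

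Besides Fosb and Per1, the 10 largest rises by the naming rule included 6 that held under each setting and each library left out. These were Atf3, a stress-induced transcription factor (log2 fold change 3.72, SE 0.37), and Cyr61, a secreted matricellular protein (3.38, SE 0.32). The others were Egr3, a zinc-finger transcription factor (2.91, SE 0.24), Arc, a cytoskeleton-associated protein (2.71, SE 0.26), and Ptgs2, the inducible cyclooxygenase (2.51, SE 0.30). Errfi1, a feedback inhibitor of the EGF receptor, was the last of them (2.61, SE 0.31). The adjusted p of these 6 genes lay between 6.1e-05 and 0.0011. Ankrd1, with 30 counts summed over vehicle, rose by 4.01 (SE 0.79, adjusted p = 0.032). Its call was lost without vehicle 1, 2 or 3, 1 h library 1 or 24 h library 2 (adjusted p up to 0.16), with no filter, with voom and with the GC correction (up to 0.19).

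Of the 10 largest falls, those of Socs3, Socs1 and Gas1 held under each setting and each library left out. Socs1, a relative of Socs3, fell from 37.4 ± 9.94 to 15.2 ± 0.395 CPM (-1.30, SE 0.19, adjusted p = 0.0020). Gas1, a membrane protein linked to growth arrest, fell from 141 ± 16.3 to 66.9 ± 7.95 CPM (-1.07, SE 0.12, adjusted p = 2.8e-04). The remaining 7 had log2 fold changes between -1.29 and -1.01 and lost their call without at least 1 library. Without vehicle library 2, the adjusted p was 0.16 for Kctd21 and 0.083 for Wnt9a. Without vehicle library 1 it was 0.12 for Dlx4 and 0.15 for Hoxb3. Without 1 h library 3 it was 0.063 for Gper1, an oestrogen-responsive G protein-coupled receptor, and 0.12 for Zfp30. Without 1 h library 1 it was 0.064 for Apol9b, which has a near-identical neighbouring paralogue.

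**Figure D1:**
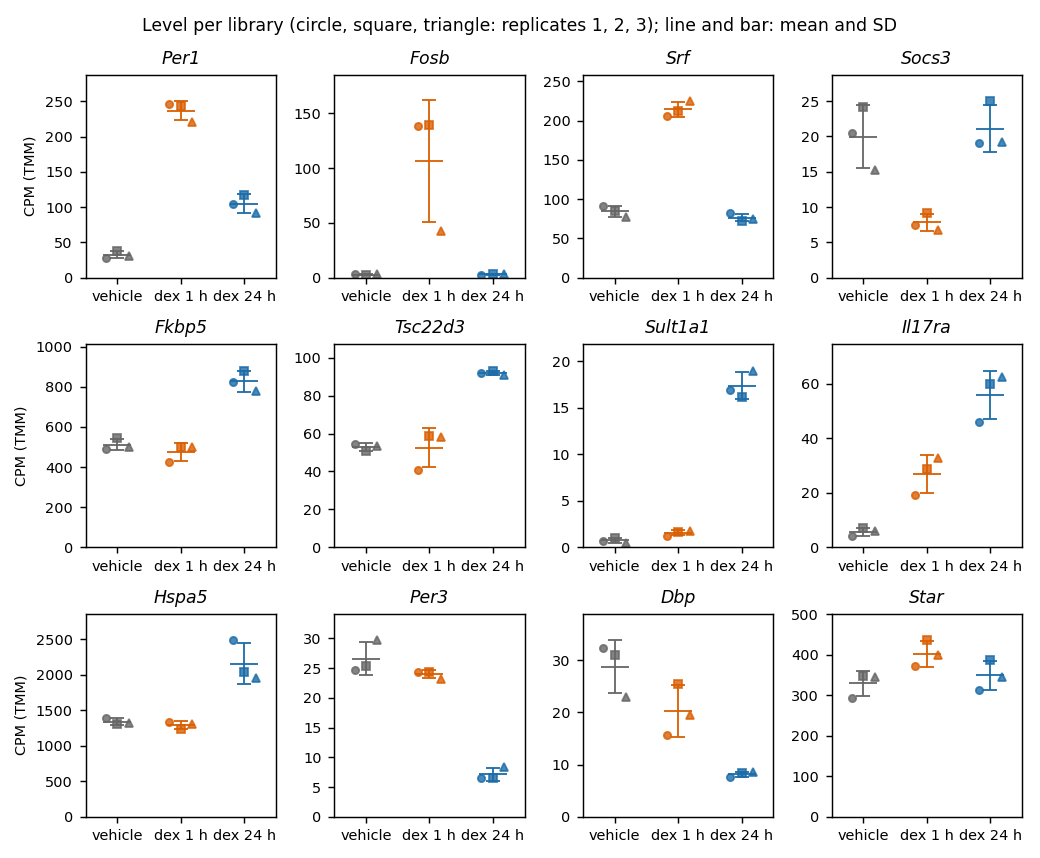
Normalised level (CPM, linear axis from 0) of 12 genes in each of the 9 libraries by group; circles, squares and triangles are replicates 1, 2 and 3, lines are means and bars SD of n = 3. Fosb averaged 106 CPM at 1 h against 2.91 in vehicle and 3.02 at 24 h, while Sult1a1 averaged 17.4 CPM at 24 h against 0.730 in vehicle.

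Among the 35 gene lists, the immediate early genes, which respond to stimuli without new protein synthesis, moved furthest at 1 h. Of 23 tested members, 12 rose and 0 fell (17 rose adjusted over the list alone), with a median log2 fold change of 1.34 (camera adjusted p = 1.9e-49). Examples are Btg2, an antiproliferative gene (1.48, SE 0.12, adjusted p = 2.0e-05), and Nr4a1, an orphan nuclear receptor that responds to ACTH (2.48, SE 0.21, adjusted p = 8.6e-05). Of 17 actin cytoskeleton genes, 6 rose (9 adjusted over the list alone; camera adjusted p = 2.8e-16). They included the focal adhesion protein Zyx (0.75, SE 0.09), the calponin Cnn2 (0.80, SE 0.10) and the LIM protein Fhl2 (0.89, SE 0.11). Of 21 circadian clock genes, 3 rose, namely Per1, the repressor Nfil3 (1.62, SE 0.14, adjusted p = 2.8e-05) and Bhlhe41 (0.79, SE 0.13, adjusted p = 0.0044). Of these 5 rose adjusted over the list alone, and the camera adjusted p was 4.5e-08. These 3 lists held with an estimated correlation (adjusted p = 0.011, 0.023 and 0.011), and the actin call was lost there with the GC correction (adjusted p = 0.058) but not with the block as well (0.046). Bhlhe41 overlaps the gene model Gm43909, which passed the same test (1.12, adjusted p = 0.016), and the strand setting of the counting is not given in the sources used here.

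Of 27 glucocorticoid receptor induced genes, 5 rose at 1 h (8 adjusted over the list alone; camera adjusted p = 6.0e-11). The list had adjusted p = 0.080 with an estimated correlation, and 0.069 there with the replicate block, 0.053 with the GC correction and 0.046 with both. The 5 were Per1, Errfi1, Zfp36, the MAP kinase phosphatase Dusp1 (1.89, SE 0.17, adjusted p = 3.9e-05) and the NF-kappaB inhibitor Nfkbia (0.98, SE 0.17, adjusted p = 0.0063). Dusp1 and Zfp36 also stand on the immediate early list, Per1 on the clock list and Errfi1 on the MAP kinase feedback list. Camera called those lists at 1 h too, so this list is not separate support for a receptor response. Fkbp5 and Tsc22d3, a co-chaperone of steroid receptors and the leucine zipper GILZ, had log2 fold changes of -0.11 (SE 0.10, adjusted p = 0.65) and -0.01 (SE 0.13, adjusted p = 0.99).

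A further 7 lists were higher at 1 h by camera but lost the call with an estimated correlation, though with the GC correction and the replicate block the ATF4 and TGF-beta lists kept it there (adjusted p = 0.046 each). MAP kinase feedback had 4 of 19 members higher (5 higher and 2 lower adjusted over the list alone; adjusted p = 3.9e-04 and adjusted p = 0.22 with an estimated correlation). The 4 were Errfi1 and the phosphatases Dusp8 (1.63, SE 0.17), Dusp10 (1.83, SE 0.28) and Dusp16 (0.54, SE 0.11). Of 20 ATF4 amino acid response genes 2 rose, Mthfd2, a mitochondrial folate enzyme (0.72, SE 0.10), and the amino acid transporter Slc7a1 (0.47, SE 0.10). On that list 3 rose adjusted over the list alone (adjusted p = 4.8e-05 and adjusted p = 0.22 with an estimated correlation). Of 15 TGF-beta and BMP signalling genes 3 rose, among them Tgfb2 (0.64, SE 0.10) and Skil (1.11, SE 0.21); 7 rose and 1 fell adjusted over the list alone (adjusted p = 3.9e-04 and adjusted p = 0.19 with an estimated correlation). Of 13 YAP targets 3 rose, Amotl2 (1.32, SE 0.15), Cyr61 and Ankrd1, with 3 higher and 1 lower adjusted over the list alone. Its median log2 fold change was -0.07 and its mean 0.61 (adjusted p = 0.0072 and adjusted p = 0.35 with an estimated correlation). Of 21 adrenocortical regulators and ACTH signalling genes 3 rose, Nr4a1, Nr4a3 (1.17, SE 0.23) and the transcriptional coregulator Cited2 (1.30, SE 0.14). There 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.014 and adjusted p = 0.35 with an estimated correlation). Of 11 inflammatory genes that glucocorticoids repress elsewhere, the cytokine Lif (1.99, SE 0.21) and Ptgs2 rose and Irf1 (-0.93, SE 0.17) fell, so the members called moved against the list's name as well as with it. That list had 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.022 and adjusted p = 0.19 with an estimated correlation). The mitochondrial genome's 13 genes had a median of 0.29 with 0 called by edgeR, DESeq2 or voom and 0 at an unadjusted p under 0.05, also adjusted over the list alone (adjusted p = 0.028 and adjusted p = 0.54 with an estimated correlation).

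The replicate block called 5 ATF4 genes and 5 TGF-beta genes higher, and 1 MAP kinase feedback gene and 1 adrenocortical regulator lower. Without vehicle library 3 the call of 4 of these lists was lost, with adjusted p = 0.24 for the adrenocortical regulators, 0.22 for YAP targets, 0.18 for the inflammatory genes and 0.057 for TGF-beta and BMP signalling. The inflammatory call was also lost without 1 h library 2, and the mitochondrial call was lost with the GC correction and without vehicle 1, vehicle 2 or 1 h library 1 (adjusted p = 0.51 for the last). The mitochondrial median was 0.06 with the GC correction and 0.04 with the block as well.

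Cell cycle lists were lower at 1 h by camera and lost the call with an estimated correlation, though with the GC correction and the replicate block mitosis kept it there (adjusted p = 0.046, 12 lower). Of 26 mitosis genes, the kinase Plk1 fell (-0.74, SE 0.11, adjusted p = 0.0024) and 7 fell adjusted over the list alone, with a median of -0.14 (adjusted p = 1.5e-05 and adjusted p = 0.40 with an estimated correlation). Of 30 S phase and DNA replication genes 0 were called by edgeR or voom, 1 was lower by DESeq2 and 11 were lower at an unadjusted p under 0.05; 0 passed adjusted over the list alone. The list's median was -0.16 (adjusted p = 1.1e-04 and adjusted p = 0.40 with an estimated correlation). Of 11 cyclin-dependent kinase inhibitors and G1 cyclins, Cdkn1b, which encodes p27, fell (-0.59, SE 0.10, adjusted p = 0.0048), with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0063 and adjusted p = 0.22 with an estimated correlation). That list mixes inhibitors, such as Cdkn1b, with cyclins, so its direction gives no direction for the cell cycle. The 17 unfolded protein response genes had a median of -0.18, with 0 called by edgeR or voom, 1 lower by DESeq2, 4 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (adjusted p = 0.0045 and adjusted p = 0.37 with an estimated correlation). Lower when the replicate block was fitted were 7 mitosis genes, 2 S phase genes, 2 cyclin-dependent kinase inhibitors or G1 cyclins and 3 unfolded protein response genes.

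The other 18 lists tested did not pass at 1 h. Hypoxia and glycolysis had adjusted p = 0.10, and adjusted p = 0.0036 lower with the replicate block, which was lost there with an estimated correlation (adjusted p = 0.46). The adjusted p was 0.88 for steroidogenesis and also for the corticosteroid receptors, chaperones and 11-beta-hydroxysteroid dehydrogenases, 0.76 for cholesterol biosynthesis and uptake and 0.35 for fatty acid synthesis. It was 0.39 for p53 targets (Btg2 higher, Bbc3 lower), 0.53 for the BCL2 family (Mcl1 higher, Bbc3 lower), 0.35 for the heat shock response and 0.22 for the oxidative stress response (Gclc higher). It was 0.94 for Wnt signalling and zona glomerulosa, 0.94 for extracellular matrix and adhesion, 0.20 for interferon stimulated genes and 0.17 for growth factor receptors and ligands (Hbegf higher). It was 0.22 for ion channels and pumps, 0.90 for fibroblast and capsule markers, 0.90 for endothelial markers, 0.69 for replication dependent histones and 0.17 for ribosomal proteins. Btg2 held without each library. The calls of Bbc3, Mcl1, Gclc and Hbegf, and of Nr4a3, Irf1, Dusp16, Slc7a1 and Skil above, were lost without at least 1 library, most often vehicle 1, vehicle 2, 1 h library 1 or 1 h library 3. Without vehicle library 2 the adjusted p was 0.28 for Bbc3, 0.17 for Dusp16 and Slc7a1, 0.10 for Hbegf and 0.095 for Nr4a3. Without vehicle library 1 it was 0.17 for Mcl1, 0.14 for Gclc and 0.093 for Skil, and without 1 h library 3 it was 0.081 for Irf1. Hbegf also had adjusted p = 0.057 at most in other settings, which were the GC correction and the comparison of only 2 groups. Adrenal medulla markers and macrophage and leukocyte markers had 3 tested members each of 14 and 13, too few for the list test, and 0 of these were called at 1 h or 24 h by edgeR, DESeq2 or voom. At an unadjusted p under 0.05, 1 medulla marker was higher at each time and 1 macrophage marker at 24 h.

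**Figure D2:**
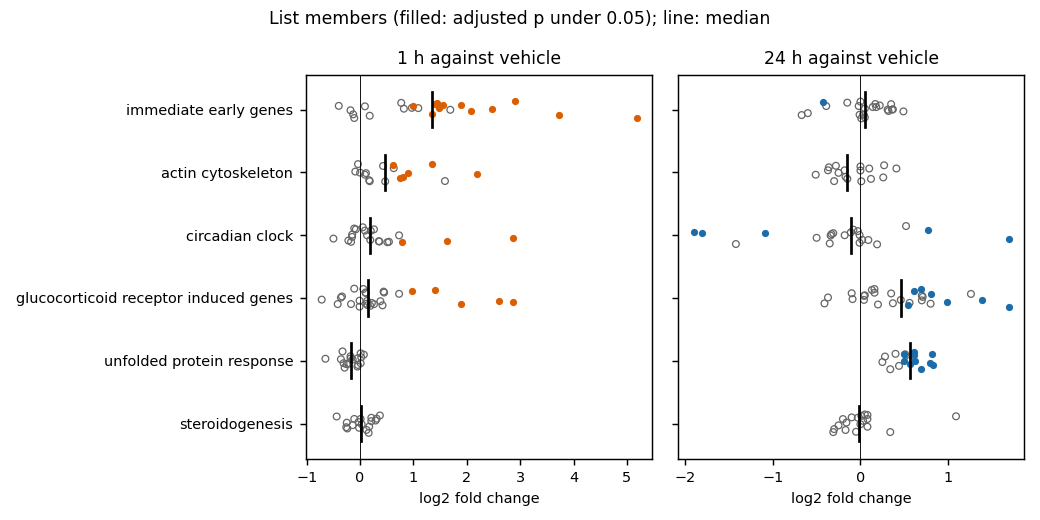
Log2 fold change of each tested member of 6 gene lists, at 1 h (left) and at 24 h (right) against vehicle; filled points passed the edgeR test, open points did not, and black lines are list medians. The immediate early genes had a median of 1.34 at 1 h and 0.05 at 24 h, and the unfolded protein response genes -0.18 and 0.56.

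The second comparison asked which transcripts differed from vehicle after 24 h of dexamethasone. Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432), a phenol sulfotransferase, rose from 0.730 ± 0.245 to 17.4 ± 1.47 CPM (log2 fold change 4.59, SE 0.26, adjusted p = 7.8e-07). Scnn1b (ENSMUSG00000030873, chromosome 7, 121865038 to 121918514), which encodes the beta subunit of the epithelial sodium channel, rose from 0.237 ± 0.214 to 5.12 ± 1.93 CPM (4.34, SE 0.66, adjusted p = 0.0038). The clock genes Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), Dbp and Tef fell. Per3 went from 26.6 ± 2.67 to 7.12 ± 1.04 CPM (-1.90, SE 0.15, adjusted p = 1.3e-05). Among glucocorticoid receptor targets, Fkbp5 rose from 512 ± 28.3 to 827 ± 51.8 CPM (0.69, SE 0.10, adjusted p = 0.0023) and Tsc22d3 from 52.9 ± 1.96 to 92.1 ± 1.17 CPM (0.80, SE 0.13, adjusted p = 0.0054).

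In all, 204 genes changed at 24 h, 140 higher and 64 lower, and 73 by at least 2-fold (57 higher, 16 lower). The groups did not overlap for any of the 204, and for 14.3% of all genes tested, where chance gives 10%. With the replicate block 419 genes passed, and with the GC correction 355. Without 1 library the count was 111 (vehicle 1), 84 (vehicle 2), 101 (24 h library 1) or 83 (24 h library 2). Lower genes numbered 30, 19, 20 and 23 in these, in that order, against 64 with all libraries.

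Of the 10 largest rises at 24 h, 6 held under each setting and each library left out. Besides Sult1a1 and Scnn1b, these were the cytokine receptor Il17ra (3.31, SE 0.23, adjusted p = 1.3e-05), Fam180a (4.27, SE 0.72, adjusted p = 0.0074), the gonadotropin-releasing hormone receptor Gnrhr (2.32, SE 0.32, adjusted p = 0.0017) and the chromatin remodelling ATPase Smarca1 (1.97, SE 0.21, adjusted p = 6.0e-04). Il17ra rose from 5.67 ± 1.52 to 56.0 ± 8.81 CPM. Counts were few in vehicle: summed over 3 libraries there were 37 for Sult1a1, 13 for Scnn1b, 7 for Fam180a and 46 for Gnrhr. Cp, which encodes ceruloplasmin, rose from 34.0 ± 13.9 to 208 ± 65.6 CPM (2.61, SE 0.39, adjusted p = 0.0072), with adjusted p = 0.14 without 24 h library 3 and 0.11 with no filter. The calls of Olfr1033 (2.34, SE 0.47), Sptbn5 (1.97, SE 0.44) and the amylase Amy1 (1.84, SE 0.32), which has close paralogues, were also lost without 1 library. The highest adjusted p was 0.10 without vehicle library 1, 0.21 without 24 h library 2 and 0.064 without vehicle library 2.

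Of the 10 largest falls at 24 h, Per3, Dbp, Igfbp5 and Tef held under each setting and each library left out. Dbp and Tef encode PAR bZIP transcription factors of the clock output. Dbp fell from 28.7 ± 5.13 to 8.14 ± 0.509 CPM (-1.81, SE 0.19, adjusted p = 1.7e-04) and Tef from 149 ± 16.2 to 70.2 ± 1.18 CPM (-1.09, SE 0.11, adjusted p = 1.2e-04). Igfbp5, a binding protein of insulin-like growth factors, fell from 10.6 ± 0.917 to 4.40 ± 0.955 CPM (-1.26, SE 0.20, adjusted p = 0.0056). The other 6 had log2 fold changes between -1.36 and -1.14 and lost their call without at least 1 library. Without vehicle library 2 the adjusted p was 0.16 for the cadherin Cdh15, 0.12 for the potassium channel Kcnh1 and 0.064 for Tmcc3. Without 24 h library 2 it was 0.086 for Plekhh2, 0.054 for Apol9b and 0.20 for Zfp185.

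Unfolded protein response genes, which encode folding factors of the endoplasmic reticulum, rose together at 24 h. Of 17 tested members 10 rose and all 17 did adjusted over the list alone, with a median log2 fold change of 0.56 (camera adjusted p = 8.4e-31). The chaperone Hspa5, also called BiP, rose from 1338 ± 50.8 to 2157 ± 289 CPM (0.69, SE 0.11, adjusted p = 0.0040). Manf rose by 0.82 (SE 0.13) and the disulfide isomerases Pdia6 and Pdia4 by 0.61 each (SE 0.10 and 0.11). Of the lists called at 24 h, this one held with an estimated correlation (adjusted p = 0.044), but not there with the replicate block (adjusted p = 0.13), the GC correction (0.058) or both (0.15). Pdia4 had adjusted p = 0.052 without 24 h library 2.

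Glucocorticoid receptor induced genes were also higher at 24 h, 7 of 27 over all genes tested and 14 adjusted over the list alone, with 1 lower there (median 0.46, camera adjusted p = 1.2e-17). The list call was lost, at adjusted p = 0.052 with an estimated correlation and 0.13 there with the replicate block, which called 11 members higher and 1 lower. Per1 was still higher (1.69, SE 0.13, adjusted p = 1.3e-05), and Map3k6, a stress-activated kinase, rose from 24.1 ± 2.78 to 47.6 ± 4.22 CPM (0.99, SE 0.13, adjusted p = 0.0016). The rest were Fkbp5, Tsc22d3, Glul, Hif3a and Sesn1, and Sesn1 had adjusted p = 0.14 without 24 h library 2.

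Circadian clock genes went both ways at 24 h: Per1 and Arntl rose and Per3, Tef and Dbp fell, out of 21 tested (3 higher and 5 lower adjusted over the list alone). The list was lower by camera (adjusted p = 0.0026, and adjusted p = 0.095 with an estimated correlation). Extracellular matrix and adhesion genes were lower (median -0.18, adjusted p = 4.6e-04, and adjusted p = 0.16 with an estimated correlation). Of 20 tested, the collagen Col1a1 (-1.03, SE 0.12, adjusted p = 5.4e-04) and the metalloproteinase inhibitor Timp3 (-0.81, SE 0.10, adjusted p = 9.3e-04) fell and Col5a1 rose (0.51, SE 0.12), with 1 higher and 4 lower adjusted over the list alone. Of 13 YAP targets Ajuba fell (-0.64, SE 0.14) and 2 fell adjusted over the list alone (adjusted p = 0.045 and adjusted p = 0.62 with an estimated correlation). The YAP call was lost with the GC correction and without vehicle library 1 or 24 h library 3 (adjusted p = 0.28 for the last). Col5a1 and Ajuba had adjusted p = 0.20 without 24 h library 2 and 0.19 without vehicle library 2.

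Of 20 ATF4 amino acid response genes, Mthfd2 rose from 77.5 ± 7.37 to 166 ± 12.8 CPM (1.10, SE 0.10, adjusted p = 6.3e-05) and 4 rose adjusted over the list alone (adjusted p = 1.6e-07 and adjusted p = 0.16 with an estimated correlation). Cholesterol biosynthesis and uptake genes had a median of 0.25, with 21 of 25 positive. Of these 0 were called by edgeR, DESeq2 or voom or adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05 (camera adjusted p = 2.3e-04 and adjusted p = 0.62 with an estimated correlation). Fitting the replicate block called 1 cholesterol gene and 3 ATF4 genes higher, 5 extracellular matrix genes lower and 1 higher, and 2 YAP targets lower.

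The other 26 lists tested did not pass at 24 h. The immediate early genes had a median of 0.05 (adjusted p = 0.99), with Fosl2 lower (-0.43, SE 0.09), and the actin cytoskeleton genes -0.15 (adjusted p = 0.11). The adjusted p was 0.83 for steroidogenesis, 0.84 for adrenocortical regulators (Mrap higher), 0.66 for the inflammatory genes, 0.63 for corticosteroid receptors and chaperones and 0.41 for fatty acid synthesis. It was 0.84 for MAP kinase feedback, 0.14 for S phase, 0.92 for mitosis and 0.14 for cyclin-dependent kinase inhibitors and G1 cyclins, in which the cyclin Ccnd2 fell from 42.4 ± 1.78 to 21.1 ± 0.520 CPM (-1.01, SE 0.12, adjusted p = 7.3e-04). It was 0.68 for p53 targets (Sesn1 higher, Plk2 lower), 0.99 for the BCL2 family (Bcl2l1 higher), 0.32 for heat shock, 0.99 for oxidative stress and 0.84 for hypoxia. It was 0.26 for Wnt signalling and zona glomerulosa (Shh higher), 0.38 for TGF-beta (Tgfb3 lower) and 0.89 for interferon. It was 0.83 for growth factors, 0.14 for channels and pumps and 0.088 for fibroblast markers (Col1a1 lower). It was 0.25 for endothelial markers, 0.66 for the mitochondrial genome, 0.14 for histones and 0.72 for ribosomal proteins. Of the genes named here, Fosl2, Mrap, Plk2, Bcl2l1, Shh and Tgfb3 lost their call without at least 1 library, with adjusted p = 0.24 for Fosl2 and 0.17 for Plk2 without vehicle library 2 and 0.21 for Bcl2l1 without 24 h library 1. Without 24 h library 2 it was 0.098 for Shh, 0.085 for Tgfb3 and 0.059 for Mrap.

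Steroidogenic genes did not pass the test without a block at either time. Star, which carries cholesterol into mitochondria, was 329.5 ± 30.6 CPM in vehicle, 402 ± 32.6 at 1 h (0.29, SE 0.11, adjusted p = 0.28) and 349 ± 37.0 at 24 h (0.08, SE 0.11, adjusted p = 0.99). Cyp11a1, which makes pregnenolone, had log2 fold changes of 0.03 and -0.10 (SE 0.11 each, adjusted p = 0.94 and 0.96). Cyp11b1, the 11-beta-hydroxylase, had 0.21 and -0.03 (SE 0.21 each, adjusted p = 0.68 and 1.0), and Hsd3b1 had 0.31 and -0.16 (SE 0.18 each, adjusted p = 0.48 and 0.98). Between 24 h and 1 h, Hsd3b1 differed by -0.47 (SE 0.18, adjusted p = 0.24), and with the replicate block this was adjusted p = 0.0058. Of the 18 steroidogenesis genes tested, 0 were called at 1 h by edgeR, DESeq2 or voom, and 3 had an unadjusted p under 0.05 (2 higher, 1 lower). At 24 h 0 were called by edgeR or voom, 1 was higher by DESeq2, and 2 were higher and 3 lower at an unadjusted p under 0.05. Fdx1, an electron donor of steroidogenic enzymes, was higher with the replicate block at 1 h (0.38, adjusted p = 0.026) and at 24 h (0.35, adjusted p = 0.043), and Akr1b7, an aldose reductase of the adrenal cortex, at 24 h (1.08, adjusted p = 4.0e-04). Between the treated times the block called 2 higher and 2 lower. With the GC correction and the block 3 were higher at 1 h, and 2 higher and 3 lower at 24 h.

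The following receptors and regulators of the axis, named whether called or not, also did not pass. The glucocorticoid receptor Nr3c1 was 101 ± 5.26 CPM in vehicle, with log2 fold changes of -0.09 at 1 h and -0.21 at 24 h (adjusted p = 0.71 and 0.64). The ACTH receptor Mc2r was at 2.47 ± 0.355 CPM in vehicle (0.12 and 0.50, adjusted p = 0.87 and 0.68). The steroidogenic factor Nr5a1 (-0.26 and -0.18, adjusted p = 0.42 and 0.90), the lipoprotein receptor Scarb1 (-0.14 and -0.25, adjusted p = 0.57 and 0.49) and Hsd11b2 (-0.09 and -0.52, adjusted p = 0.96 and 0.98) behaved alike in this respect. The mineralocorticoid receptor Nr3c2 and Hsd11b1 had 14 counts each over the 9 libraries and Cyp21a1 had 5, too few to test. Nr0b1 had 0 counts, which allows up to 0.0195 CPM over all libraries pooled, counting error only.

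The third comparison tested the difference between the 24 h and 1 h dexamethasone groups itself. These groups also differed in time in culture, which the design cannot separate from the length of treatment. Fosb differed by -5.13 (SE 0.43, adjusted p = 8.1e-05), Cyr61 by -3.64 (SE 0.33, adjusted p = 1.4e-04) and Srf by -1.49 (SE 0.10, adjusted p = 4.8e-06). Scnn1b was higher by 4.88 (SE 0.69, adjusted p = 0.0012), Sult1a1 by 3.47 (SE 0.23, adjusted p = 4.8e-06), Gnrhr by 1.92 (SE 0.31, adjusted p = 0.0032) and S100a6, a calcium-binding protein, by 1.56 (SE 0.12, adjusted p = 1.3e-05). Fkbp5 and Tsc22d3 were higher by 0.80 (SE 0.10, adjusted p = 4.0e-04) and 0.81 (SE 0.13, adjusted p = 0.0027), and Per1 was lower by 1.17 on the log2 scale (-1.17, SE 0.13, adjusted p = 1.2e-04).

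In all, 453 genes differed between the treated times, 207 higher and 246 lower at 24 h, 131 by at least 2-fold (42 higher, 89 lower). The groups did not overlap for 452 of them and for 20.2% of all genes tested, where chance gives 10%. Of the 453 genes, 196 were called in neither comparison against vehicle. With the replicate block 913 genes passed, and with the GC correction 793. Without 1 library the count was 231 (1 h library 3), 212 (24 h library 1) or 191 (24 h library 2). Of the 10 genes that the naming rule takes by size, Cp had adjusted p = 0.12 without 24 h library 3, Ankrd1 0.11 and Thbs1, a matrix glycoprotein with 9 counts at 24 h, 0.19 without 24 h library 2.

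Of 33 lists, 11 passed between the treated times and 4 held with an estimated correlation. Immediate early genes had 13 of 23 members lower (1 higher and 19 lower adjusted over the list alone; median -1.08, adjusted p = 4.8e-43 and 0.0091). Unfolded protein response genes had 14 of 17 higher and 17 adjusted over the list alone (median 0.68, adjusted p = 1.7e-34 and 0.0091), among them Sdf2l1 (1.44, SE 0.15), Pdia4 (0.94, SE 0.11) and the calcium-binding chaperone Calr (0.92, SE 0.13). Actin cytoskeleton genes had 6 of 17 lower and 13 adjusted over the list alone (median -0.47, adjusted p = 1.2e-20 and 0.0091). Circadian clock genes had 9 of 21 lower, with Arntl higher, and 14 lower and 1 higher adjusted over the list alone (median -0.71, adjusted p = 1.7e-16 and 0.0029). In each pair the second adjusted p is with an estimated correlation, where the actin call was lost with the GC correction (adjusted p = 0.057). With the GC correction and the block the clock alone held there (adjusted p = 0.029), and immediate early genes (0.076), the unfolded protein response (0.076) and the actin cytoskeleton (0.058) were lost.

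The other 7 lists lost the call with an estimated correlation, but 2 kept it there with the replicate block, TGF-beta and BMP signalling (adjusted p = 0.035) and YAP targets (0.028). These were lost again when the GC correction was added to the block (adjusted p = 0.058 and 0.094). TGF-beta and BMP signalling had 3 of 15 lower, 4 adjusted over the list alone (adjusted p = 1.7e-05 and adjusted p = 0.10 with an estimated correlation), with Tgfb2 lower by 1.01 (-1.01, SE 0.10). YAP targets had 3 of 13 lower, also adjusted over the list alone (adjusted p = 1.1e-05 and adjusted p = 0.11 with an estimated correlation). Mitosis had Plk1 (0.67, SE 0.11) and Aurka higher of 26, and 9 higher adjusted over the list alone (adjusted p = 2.6e-05 and adjusted p = 0.56 with an estimated correlation). Extracellular matrix had 5 of 20 lower, Timp3, Col1a1, Tnc, Thbs1 and Lama1, and Col5a1 higher, with the same counts adjusted over the list alone (adjusted p = 0.0042 and adjusted p = 0.16 with an estimated correlation). MAP kinase feedback had 4 of 19 lower, and 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.0042 and adjusted p = 0.31 with an estimated correlation). Its adjusted p was 0.077 without 24 h library 3. Ion channels and pumps had the calcium pump Atp2b3 (-0.96, SE 0.14) and Cacna1c lower of 13, 3 adjusted over the list alone (adjusted p = 0.0085 and adjusted p = 0.10 with an estimated correlation). Cholesterol biosynthesis had Mvd higher of 25, and 1 adjusted over the list alone (adjusted p = 0.011 and adjusted p = 0.65 with an estimated correlation; 0.55 without 1 h library 1).

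With the replicate block 9 mitosis genes and 2 cholesterol genes were higher, 5 TGF-beta genes were lower, and 1 MAP kinase feedback gene was higher. In that fit 4 more lists passed this comparison. These were hypoxia and glycolysis, higher (adjusted p = 0.075, with the block 8.6e-04), fibroblast and capsule markers, lower (0.076, with the block 0.016), fatty acid synthesis, higher (0.076, with the block 0.026), and S phase, higher (0.058, with the block 0.044). With the block and an estimated correlation all 4 were lost (adjusted p = 0.45, 0.23, 0.45 and 0.52). The rest of the lists tested had adjusted p between 0.059, for adrenocortical regulators, and 0.96, for heat shock. Aurka, Mvd, Cacna1c and Col5a1 lost their call in this comparison without 24 h library 1 (adjusted p = 0.21 for Aurka and 0.10 for Cacna1c) or 24 h library 2 (0.17 for Mvd and 0.077 for Col5a1), among other libraries.

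Of 131 genes higher at 1 h, 97 were lower at 24 h than at 1 h, and of 60 lower at 1 h, 28 were higher at 24 h than at 1 h. Of 140 higher at 24 h, 91 were also higher than at 1 h, and of 64 lower at 24 h, 41 were also lower than at 1 h. Both tests behind each of these shares use the same treated libraries, which alone raises the shares. They are therefore not independent support for a pattern in time. Across the 3 groups together 494 genes differed, 1023 with the replicate block and 840 with the GC correction. Without 1 library this was 313 (vehicle 2), 765 (vehicle 3), 293 (1 h library 3), 300 (24 h library 1) or 265 (24 h library 2).

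**Figure D3:**
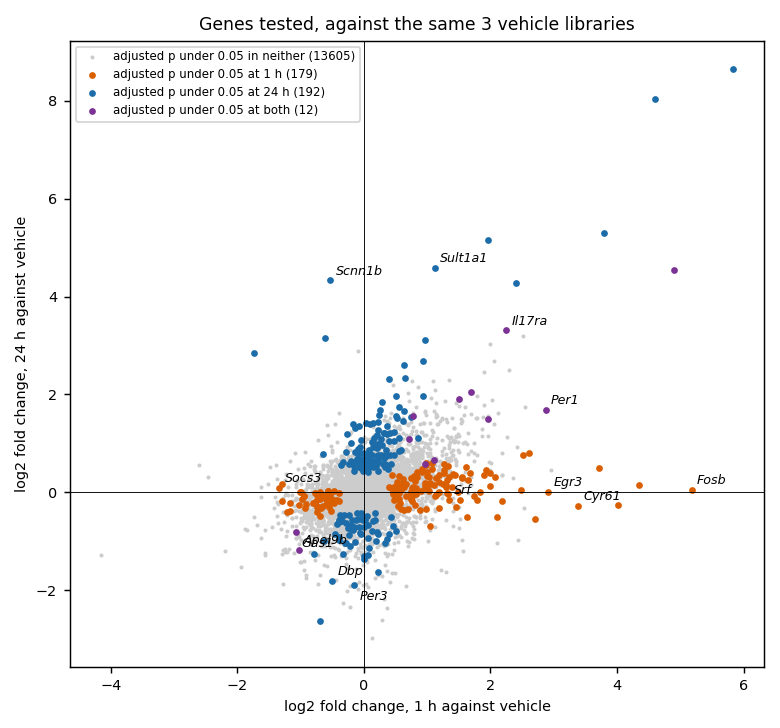
Log2 fold change against vehicle at 1 h (horizontal) and 24 h (vertical) of each gene tested, coloured by the comparison it passed; both comparisons share the 3 vehicle libraries. The 12 genes called at both times include Per1 (2.87 and 1.69) and Il17ra (2.25 and 3.31), while Fosb (5.18 and 0.05) was called at 1 h and Per3 (-0.15 and -1.90) at 24 h.

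At both times 10 genes were higher and 2 lower than vehicle, where independent calls would give 1.31 and 0.275. Both comparisons used the same 3 vehicle libraries, which alone correlates them and which are too few to split. The correlation of log2 fold changes across genes was 0.42, below the mean of 0.50 in 20 simulations of unchanged groups with shared controls, while the covariance was 0.0628 against 0.0418. Those simulations gave a mean of 0.05 shared genes, but unchanged groups have almost no calls to share, so this is no reference for the 12. The independent value leaves out the shared vehicles, and part of the excess over it can come from them. The genes higher at both times were Per1, Il17ra, Mthfd2, Gadd45b (1.11 and 0.67), Slc45a3 (0.78 and 1.57), Pdp1, Tent5b, 9330159F19Rik, Gm2420 and Gm27252, and those lower were Gas1 (-1.07 and -0.82) and Apol9b (-1.03 and -1.17). Il17ra was higher at 24 h than at 1 h by 1.05 (SE 0.20, adjusted p = 0.012), and Slc45a3 by 0.79 (adjusted p = 0.014). With the replicate block 38 genes were shared and with the GC correction 25. Without vehicle 1, vehicle 2 or 24 h library 2 there were 7, and without vehicle 3 there were 20.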

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

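The tests of GC bias within groups, of time in culture and of clock phase, and the GC correction, were chosen after the results were seen. The results in this part are here because they differed between 24 h and 1 h in the comparison of the 2 treated groups. The vehicle cancels in that comparison. Its 2 groups also differ in time in culture, which the design cannot separate from the length of treatment. In it 453 genes passed, of which 196 passed in neither comparison against vehicle. In 1 of the 10 splits of these 6 libraries as many genes passed, the real split, and the highest of the others gave 0; the splits are too few for a share under 0.05. The same holds at 1 h against vehicle (1 of 10 splits; 191, highest other 0) and at 24 h against vehicle (1 of 10; 204, highest other 1). Among 100 of the 280 splits of all 9 libraries into 3 groups, 1 gave as many as 494, the real one, and the highest other gave 157. A share of 1 in 100 makes chance unlikely for the 3 groups together but does not exclude it. These splits moved libraries freely and left out the pairing by replicate number. The split by replicate number gave 28.

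Of the gene lists, 11 differed between the times. The mean log2 fold change at 24 h minus that at 1 h was 0.72 for the unfolded protein response, 0.2 for mitosis and 0.18 for cholesterol biosynthesis and uptake. It was -1.32 for immediate early genes, -0.77 for YAP targets, -0.68 for the actin cytoskeleton, -0.6 for the circadian clock, -0.54 for TGF-beta and BMP signalling, -0.41 for MAP kinase feedback, -0.34 for extracellular matrix and adhesion and -0.21 for ion channels and pumps. Over the other settings and libraries left out, this mean ran from 0.10 to 0.28 for mitosis and from 0.06 to 0.27 for cholesterol. With an estimated correlation the call held for immediate early genes, the unfolded protein response, the actin cytoskeleton and the circadian clock. That of the actin cytoskeleton was lost there with the GC correction (adjusted p = 0.057). With the GC correction and the replicate block only the clock kept it (0.029), and immediate early genes and the unfolded protein response (0.076 each) and the actin cytoskeleton (0.058) lost it.

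Of the genes named by rule, those in this paragraph were higher at 24 h than at 1 h. The log2 differences were 4.88 for Scnn1b, 3.47 for Sult1a1, 1.98 for Cp, 1.92 for Gnrhr, 1.56 for S100a6, 1.55 for Amy1, 1.46 for Smarca1, 1.46 for Kctd21, 1.44 for Sdf2l1, 1.43 for Socs3 and 1.12 for Socs1. They were 1.05 for Il17ra, 1.00 for Zfp30, 0.96 for Manf, 0.95 for Gper1, 0.94 for Pdia4, 0.92 for Calr, 0.81 for Mvd, 0.81 for Tsc22d3, 0.80 for Fkbp5 and 0.79 for Pdia6. Smaller differences were 0.77 for Cdkn2d, 0.76 for Map3k6, 0.74 for Hspa5, 0.67 for Plk1, 0.58 for Col5a1, 0.53 for Mrap, 0.50 for Shh, 0.50 for Aurka, 0.49 for Psrc1, 0.43 for Cdkn1b and 0.43 for Sesn1. The call was lost without 24 h library 2 for Sesn1 (adjusted p = 0.27), Mrap (0.24), Psrc1 (0.19), Mvd (0.17), Shh (0.17), Cdkn1b (0.15) and Col5a1 (0.077), among other libraries for each. It was lost without 24 h library 1 for Aurka (0.21) and Cdkn2d (0.059), and without 24 h library 3 for Cp (0.12). Slc45a3, named outside the rule because it rose at both times, differed by 0.79, and other genes named outside the rule are not listed here.

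The other genes named by rule and given here were lower at 24 h than at 1 h. The log2 differences were -5.13 for Fosb, -4.26 for Ankrd1, -3.64 for Cyr61, -3.41 for Thbs1, -3.26 for Arc, -3.23 for Atf3, -2.89 for Egr3, -2.44 for Nr4a1, -2.13 for Dusp8 and -1.94 for Hbegf. They were -1.86 for Lif, -1.82 for Dusp10, -1.81 for Errfi1, -1.76 for Ptgs2, -1.74 for Per3, -1.54 for Dusp1, -1.49 for Srf, -1.49 for Btg2, -1.36 for Cdh15, -1.34 for Kcnh1 and -1.33 for Amotl2. Next came -1.31 for Plekhh2, -1.31 for Dbp, -1.26 for Fhl2, -1.22 for Zfp185, -1.18 for Nr4a3, -1.17 for Per1, -1.15 for Cited2, -1.14 for Hist1h1c, -1.09 for Nfil3, -1.05 for Cnn2 and -1.01 for Timp3. Then there were -1.01 for Tgfb2, -0.97 for Skil, -0.96 for Atp2b3, -0.95 for Tnc, -0.93 for Igfbp5, -0.92 for Plk2, -0.87 for Ccnd2, -0.87 for Tef, -0.82 for Dusp16, -0.81 for Hist1h2bc and -0.77 for Bhlhe41. The smallest were -0.76 for Igf1, -0.75 for Zyx, -0.73 for Col1a1, -0.73 for Gsta4, -0.60 for Gclc, -0.49 for Cacna1c and -0.46 for Gpam. The call was lost without 24 h library 2 for Thbs1 (adjusted p = 0.19), Hist1h1c (0.19), Skil (0.12), Ankrd1 (0.11), Nr4a3 (0.065) and Gsta4 (0.065). It was lost without 24 h library 1 for Hist1h2bc (0.18), Cacna1c (0.10) and Gpam (0.080), without 24 h library 3 for Errfi1 (0.062), and with only the 2 groups compared for Hbegf (0.051). Hist1h1c was at -0.65 without 1 h library 2. Genes that the rule chose only for another comparison were not tried in this one without each library.

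The rise of immediate early genes at 1 h was uneven among the treated libraries. Egr1 held 638, 265 and 194 CPM in 1 h libraries 1, 2 and 3 (log2 fold change 0.97, adjusted p = 0.25) and Fosb 138, 139 and 42.6. Without 1 h library 1 the 12 called members had a median of 1.59 against 1.72 with all libraries. With the GC correction it was 1.83, and all 12 passed in both. These 12 were picked because they passed with all libraries, which leaves out uneven members such as Egr1. Over all 23 members tested the mean was 1.36, and 1.18 to 1.49 over the settings tried for lists and each library left out. For the list as a whole, these values argue against 1 h library 1 or the GC trend as the whole cause. A response to dexamethasone stays open as a hypothesis. A difference in handling between the 1 h dishes and the vehicle dishes could also raise such genes, and no value here measures it.

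Fold changes at 1 h fell with transcript GC content (rank correlation -0.39 across genes). Libraries given the same treatment also differed in such a trend in the vehicle and 24 h groups. For replicate 3 against replicates 1 and 2 it was -0.55 in vehicle and -0.53 at 24 h. This split was chosen after the GC trends of the libraries were seen, so its values are no independent test. The 1 h group was not tried in this way. The values show only that trends of this size can arise between libraries without a difference in treatment. A GC bias of libraries stays a candidate explanation that needs no treatment effect. Without vehicle library 3 the trend at 1 h was -0.50. An effect of dexamethasone on GC-rich transcripts stays open as well.

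The clock genes Per3, Dbp and Tef fell at 24 h with a median log2 fold change of -1.81, and with the GC correction -1.74, which argues against the GC trend as the whole cause. At 1 h the median was -0.22. The vehicle is labelled 1 h, so more time in culture and 24 h of dexamethasone cannot be told apart for these genes, because no vehicle of 24 h was analysed here. Of 11 clock genes picked with their directions after the values were seen, 10 moved as in an opposite phase of the clock, 4 of them past the test, but Per1, left out of the 11, rose (1.69, adjusted p = 1.3e-05), so this count decides nothing and a shift of phase stays open.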

How the results depend on the processing

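The GC correction, alone and with the block, was chosen after the results were seen. No result reversed its direction while past the threshold. Counts below are for 1 h, 24 h, 24 h against 1 h, and the 3 groups together, where the counts reported were 191, 204, 453 and 494. At an adjusted p under 0.01, a stricter threshold by construction, they were 92, 79, 180 and 218. With no filter they were 460, 407, 832 and 1081, of which 188, 202, 444 and 489 were among those reported. With DESeq2 they were 396, 339, 724 and 902 (190, 204, 453 and 494 shared). With the replicate block they were 454, 419, 913 and 1023 (191, 204, 453 and 494 shared). With the GC correction they were 298, 355, 793 and 840 (180, 199, 443 and 478 shared), and with the block as well 749, 709, 1432 and 1618. The genes called at both times, 12 as reported, numbered 34, 38, 25 and 105 with DESeq2, the block, the GC correction and the last with the block. The cause was not tested. Limma-voom, other scalings, a filter at 1 CPM and only the 2 groups compared gave counts within 1.5 times those reported.

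Leaving out each library gave 90 to 438 genes at 1 h, 83 to 255 at 24 h, 191 to 578 between the treated times, 265 to 765 among the 3 groups and 7 to 20 at both times. The lowest came without vehicle 2 at 1 h and without 24 h library 2 in the next 3, and the highest at 1 h and among the 3 groups without vehicle 3; fewer libraries lower the power by construction. Lists called ranged from 12 to 17, 7 to 8 and 11 to 16, against 15, 7 and 11 reported. With an estimated correlation 3, 1 and 4 lists were called, and with fry 8 at 1 h; the cause was not tested.

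Of genes the rule chose for the same comparison and that were called in it, 30 of 48 at 1 h, 21 of 41 at 24 h and 43 of 63 between the treated times kept the call without each library, and 30, 21 and 41 under each setting. Of lists, 3 of 15, 1 of 7 and 4 of 11 kept it under each setting changed alone. With an estimated correlation and the GC correction together, the actin cytoskeleton lost it at 1 h (adjusted p = 0.058) and between the treated times (0.057), and the unfolded protein response at 24 h (0.058). With the block as well, immediate early genes and the unfolded protein response also lost it between the treated times (0.076 each). With the GC correction and the block together, Star (adjusted p = 0.044), Hsd3b1 (0.038) and Nr3c1 (0.048) passed at 1 h and Scarb1 (0.048) at 24 h. A depth of 14288753 to 20081705 counts limits genes with few counts, such as Scnn1b with 13 counts in vehicle and Fam180a with 7.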

Other observations

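The test of chromosomes was chosen after the results were seen. Of 140 genes higher at 24 h, 11 lay on the X chromosome, where 4.04 were expected from its 404 tested genes (odds ratio 2.92, Fisher's exact p = 0.0025, adjusted p = 0.049 over 20 chromosomes). The test takes genes as independent, which genes measured in the same libraries are not. The 11 were Smarca1 (log2 fold change 1.97), Phf8 (1.35), Rbbp7 (1.22), Dgkk (1.21), Lancl3 (1.12), Tceal9 (1.04), Reps2 (1.02), Tsc22d3 (0.80), Ammecr1 (0.68), Ocrl (0.58) and Il13ra1 (0.58). Zfp185, also on the X, was lower (-1.14). The 392 X-linked genes not called at 24 h had a median of 0.02, and so did the 87 neighbours of the 11. Genes called higher were left out of both sets, so these medians cannot show whether neighbouring genes rose together. Some of the 11 do lie close to each other on the X. Smarca1 ends at 47892974 and Ocrl starts at 47912387, and Reps2 ends at 162643649 and Rbbp7 starts at 162760402. The 11 may therefore not be separate loci, as the test takes them to be.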
